A study of Mus musculus with 4 samples.

How the data were processed

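The series held 4 libraries of N2a cells in 4 groups of 1 library each: total RNA and small RNA, without and with manganese. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was removed for the total RNA libraries, and sequencing used an Illumina instrument. The treatment text is the same for all libraries, so the titles alone decided which were treated. The labels do not say whether total and small RNA came from the same culture. Per the submitters' processing notes, fastp 0.18.0, Bowtie2 and StringTie were used and the build was mm9. The notes give no role or order for these tools. The counting program, the annotation release, the circRNA caller and the miRNA caller are not given in the sources used here.

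The authors deposited 4 tables of the whole series. The mRNA table (22287 genes) and the lncRNA table (30690 transcripts) hold estimated counts, which are not whole for 13.3% of the mRNA genes, and FPKM values computed by the authors. The authors' deposited log2 fold changes in these tables are ratios of the FPKM values in which 0 was replaced by 0.001. The authors also deposited a p-value and a false discovery rate per feature, from a test that the headers do not name. The circRNA table (2253 circRNAs) holds whole junction read counts and RPM values that the authors scaled to the circRNA reads of each library, with a log2 fold change, a p-value and a false discovery rate. The miRNA table (2280 small RNAs) holds whole read counts and TPM values by the authors, which imply library totals of 10914338 and 10402153 tags, and 0 is written as 0.01. Columns were assigned to libraries by the condition in the column name together with the RNA class of the table, and 0 columns were left without a library.

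Estimated counts were rounded to whole numbers. The log2 ratio is the Mn-treated over the untreated library, from counts plus 0.5 divided by the column total. A feature counted as measured with at least 20 reads over both libraries (10 junction reads for circRNAs). The counted features had a ratio of at least 2-fold. Each ratio has an exact conditional binomial 95% interval (Clopper-Pearson). PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Where a library had 0 reads, the fold is a bound against 3 counts in that library, with the reads of the other library taken as exact. The lower end of the binomial interval is lower still, for example 46.2-fold for Zfhx2 and 4.77-fold for the circRNA of Rps6ka2. No test across samples was made, since 1 library per group gives no estimate of spread. The number of features that counting noise alone puts past 2-fold is the mean of 100 draws in which each feature's reads were divided between the libraries in proportion to the column totals. These draws leave out error in assigning reads to features that share them.

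For each gene list fixed before the data were examined, the median log2 ratio was ranked among 10000 random lists of the same size, matched on mean log2 reads in 20 bins. A list was said to stand apart outside the middle 95%. Lists with under 5 measured members are given as values only. The lysosome and interferon lists each held 1 gene with 0 reads in one library, and their medians were the same to 2 decimals with that gene at its bound. Where a symbol had several rows, the row with most reads was used, and 7 measured rows were dropped for this. The lncRNA list was meant for the lncRNA table, but that table carries transcript identifiers (30196 of Ensembl form and 494 of StringTie form) that no table used here pairs with symbols. It was therefore looked up in the mRNA table, and the rule to name lncRNAs by symbol was replaced by 2 identifiers per direction. Host genes of circRNAs were named through a gene table that held 22253 of the 22287 mRNA identifiers. The notes name mm9, but 98.0% of 2165 circRNAs with a placed host lay inside that gene's span in GRCm38. The circRNA coordinates are printed as deposited, and their build is uncertain.

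Named genes follow a rule fixed before the data were examined. It takes the 12 highest and 12 lowest named protein-coding genes with at least 100 reads in the higher library, and up to 2 highest and 2 lowest members of each described list. It also takes 8 genes of manganese handling and stress, named in advance. It takes 5 and 5 circRNAs with at least 10 reads in the higher library, 6 and 6 miRNAs with at least 50 reads, and the 5 most abundant miRNAs. Known miRNAs are those with a mouse miRBase name. Single values of 2 genes that the rule takes are not reported here.

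The ratio and list steps were tested on simulated mRNA counts for 11872 genes with 200 genes changed 3-fold. The changed genes were drawn only from genes with at least 100 reads over both libraries, and the counts held counting noise only. All changed genes (100.0%) were recovered past 2-fold, 0.36% of unchanged genes passed 2-fold, and 95.6% of the intervals of unchanged genes held the true value. Of 200 random lists without an effect 2.00% fell outside the middle 95%, and of 20 lists shifted by 0.5 on the log2 scale 100.0% were found. These lists were random genes without shared regulation or a length trend. The simulation therefore checks the computation and not how real lists behave. Alternatives were scaling by the median ratio and by edgeR's TMM, other priors and count limits, the authors' FPKM, TPM or RPM ratios, other totals, and other matching of lists. The transcript length of a gene, relative to other genes, was taken from its count over its FPKM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and R 4.3.3 with edgeR 4.0.16.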

Results

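N2a is a mouse neuroblastoma cell line that is widely used as a model of dividing neuron-like cells. Manganese is an essential metal that is toxic to neurons in excess. The series compared N2a cells cultured with 300 µM manganese for 48 h with untreated N2a cells. Each condition had 1 total RNA library, depleted of ribosomal RNA, and 1 small RNA library, which made 4 libraries in all. The total RNA libraries were read out as mRNA genes, long non-coding RNA (lncRNA) transcripts and circular RNAs (circRNAs, recognised by reads across a back-splice junction). The small RNA libraries were read out as microRNAs (miRNAs). The untreated and the Mn-treated library held 13972437 and 14606961 reads assigned to mRNA genes, 8042644 and 7295089 assigned to lncRNAs, and 11665 and 9433 junction reads of circRNAs. The small RNA libraries held 10479102 and 9943263 reads in the miRNA table. With 1 library per condition no difference below has a replicate check, and each ratio compares these libraries, not the conditions. Brackets after a value give 95% intervals that cover counting error only.

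The first comparison asked which protein-coding genes differed in abundance between Mn-treated and untreated cells. Genes of DNA replication and the replication-dependent histones were lower in the Mn-treated library as groups. So was the median of a short NF-kB and inflammatory list of 13 measured genes, but not that of a wider NF-kB pathway of 52 genes. Lysosomal and heat shock genes were higher as groups. Short presynaptic and neurodegeneration lists were too, but wider pathways of synaptic vesicles and of these diseases did not stand apart. Oasl2, an interferon-stimulated gene, was among the 12 highest named genes with at least 100 reads in the higher library, but the interferon list did not stand apart. Of 11872 genes with at least 20 reads over both libraries, 862 were at least 2-fold higher and 202 at least 2-fold lower in the Mn-treated library. Counting noise alone gave 27.0 and 25.2. The median log2 ratio of all measured genes was 0.18 with column totals as the scale, and -0.001 when the libraries were scaled by their median ratio. That scaling gave 546 higher and 327 lower genes. A log2 ratio below is therefore to be read against 0.18, the value of the middle gene.

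Among named genes with at least 100 reads in the higher library, several of the highest ratios belonged to genes with few or no reads in the untreated library. Bivm had 2 and 169 reads, a ratio of 64.9 [22.0 to 672.9], a log2 ratio of 6.02 that is 4.73 in the authors' deposited table. Dop1b had 8 and 257 reads, a log2 ratio of 4.86, and is at 2.20 in the authors' deposited table. Csrnp1 had 8 and 125 reads, a ratio of 14.1. Sh2d3c, an adaptor protein of receptor signalling, had 17 and 207 reads, a ratio of 11.3. Oasl2 had 10 and 104 reads, a ratio of 9.52 [5.20 to 21.4]. Zbed6, which lies within an intron of Zc3h11a, had 10 and 149 reads. The remaining 5 had 0 reads in the untreated library. Zfhx2 had 180 reads with manganese, at least 57.4-fold higher against a floor of 3 counts. Cmtm3 had 166 reads, at least 52.9-fold higher, and Xlr3b, a member of a multicopy family, had 138 reads, at least 44.0-fold higher. Zc3h11a had 115 reads, at least 36.7-fold higher, and Rsc1a1 had 104 reads, at least 33.2-fold higher. The estimated counts of these 5 genes were fractional, as were those of Bivm, Dop1b, Csrnp1, Sh2d3c and Zbed6. Reads of all 10 could be shared with overlapping or similar gene models, so their values are uncertain. Those of Oasl2 were whole.

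At the other end, Socs3, a feedback inhibitor of cytokine signalling, had 297 reads in the untreated and 23 in the Mn-treated library, a log2 ratio of -3.73 [-4.43 to -3.14]. Adap1 had 144 and 17 reads, a log2 ratio of -3.11. Phex had 120 and 17 reads, a log2 ratio of -2.85. Itgav, an integrin subunit, was at -2.43 with 183 and 35 reads, and Sec24d, a coat protein of vesicles that leave the endoplasmic reticulum, at -2.39 with 212 and 42. In the authors' deposited table Sec24d is at -3.25. Slc35f5 had a log2 ratio of -2.32, which is -1.63 in that table, and Rgs14 one of -2.00. Rdm1 was at -1.91 with 519 and 144 reads, and Zfp280b at -1.68 with 344 and 112. Cdc6, which loads the replicative helicase onto DNA, had 861 and 281 reads and a log2 ratio of -1.68 [-1.88 to -1.48]. Kif3b, a kinesin motor subunit, had 210 reads in the untreated and 0 in the Mn-treated library, at least 73.2-fold lower. Ash1l, a histone methyltransferase, had 200 and 0 reads, at least 69.7-fold lower. Counts were fractional in one library or both for Ash1l, Socs3, Adap1, Phex, Itgav, Sec24d, Slc35f5 and Zfp280b, so these values are uncertain too. Those of Kif3b, Rgs14, Rdm1 and Cdc6 were whole. Some genes named below, such as Bbc3, E2f1 and mt-Nd6, had fractional counts as well.

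**Figure D1:**
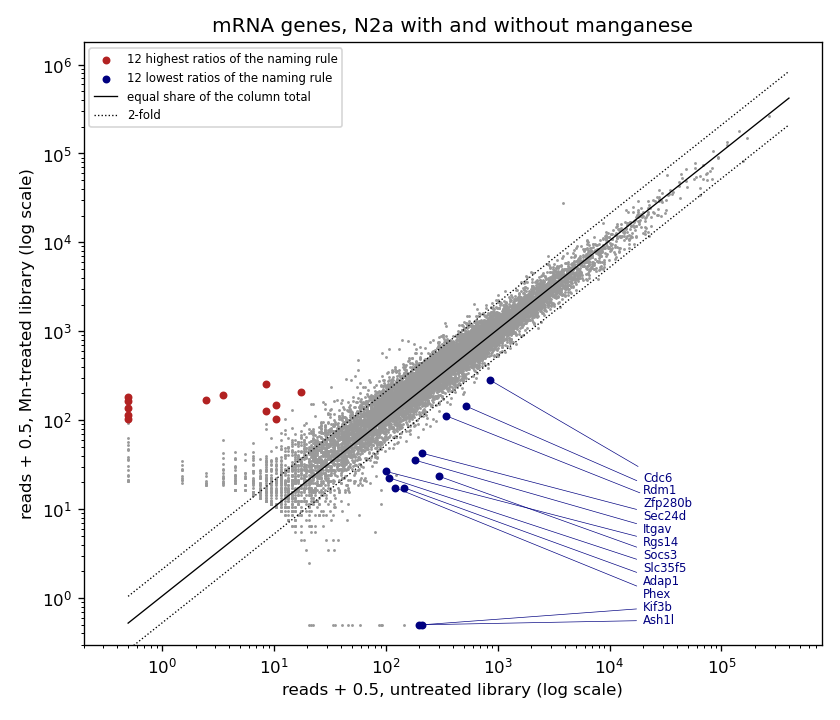
Reads plus 0.5 per mRNA gene in the untreated library (x axis, log scale) and in the Mn-treated library (y axis, log scale), 1 grey point per measured gene. The solid line marks equal shares of the column totals, the dotted lines mark 2-fold, and coloured points are the 12 highest (red) and 12 lowest (blue, with names) genes of the naming rule, with Cdc6 at 861 and 281 reads.

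The 5 measured genes of manganese handling and stress that had been named singly beforehand lay within 1.5-fold. Slc39a14, an importer of manganese, had 293 and 412 reads, a log2 ratio of 0.43 [0.21 to 0.65]. Slc11a2, a divalent metal importer, had 616 and 569 reads, at -0.18 [-0.35 to -0.01]. The importer Slc39a8 and the exporter Slc30a10 had 0 reads in both libraries, and a count of 0 allows shares of up to 2.15e-05% and 2.05e-05% of the mRNA reads. Sod2, the manganese-dependent superoxide dismutase of mitochondria, had 1723 and 1884 reads, at 0.06 [-0.03 to 0.16], and its sign turned when the libraries were scaled by their median ratio. Mt1, a metallothionein, had 0 and 4 reads. Hmox1, an oxidative stress gene, had 2352 and 3468 reads, at 0.50 [0.42 to 0.57]. Ddit3, a stress-induced transcription factor, had 939 and 1131 reads, at 0.20 [0.08 to 0.33]. Of 19 measured genes of manganese and iron transport, 3 were at least 1.5-fold higher and 1 at least 1.5-fold lower (2 and 2 with median-ratio scaling). Their median log2 ratio was 0.19, and random lists matched on expression had a median of 0.14. Slc40a1, the cellular iron exporter, had 26 and 88 reads, a log2 ratio of 1.68 [1.05 to 2.39], and Trf, transferrin, had 2 and 18, a ratio of 7.08 [2.06 to 76.5], or a log2 ratio of 2.82 against 2.10 in the authors' deposited table. Slc25a37, a mitochondrial iron importer, was at -0.79 and Steap3 at -0.46. Of 24 genes of zinc and copper handling, 5 were higher and 2 lower by 1.5-fold (4 and 2 with median-ratio scaling). Atp7a was at 1.25, but is at 0.47 in the authors' deposited table, with Slc39a10 at 0.99, while Slc30a4 was at -1.29 and the copper chaperone Atox1 at -0.76.

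Whether groups of genes shared a direction was asked with 38 lists fixed before the data were examined. Of these, 32 had at least 5 members measured among the mRNA genes. The median of each was ranked among 10000 random lists of the same size matched on mean expression. The medians of 10 lists lay above the middle 95% of their random lists and those of 5 lay below, where chance gives 1.6 lists in total. The rank compares a list with other genes of these 2 libraries, and so does not change with the scaling. The counts of members past 1.5-fold do change with it. Wider pathways named below come from the annotation in the mRNA table and were ranked, after the lists had been seen, among 1000 random lists matched on reads and transcript length.

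All 40 genes of S phase and DNA replication were measured, and their median log2 ratio was -0.57, against 0.12 for matched lists (percentile 0.00). By 1.5-fold 20 were lower and 0 higher, or 29 and 0 with median-ratio scaling. E2f1, a transcription factor of the entry into S phase, had 497 and 209 reads, at -1.31, beside Cdc6 at -1.68. The 38 replication-dependent histone genes had a median of -0.62 against -0.02 (percentile 0.00), with 21 lower by 1.5-fold and 0 higher, or 32 and 0 with median-ratio scaling. Hist2h3c2 was at -1.01 and Hist1h3g at -0.86. The highest, Hist1h4i, was at 0.06 with column totals and at -0.12 with median-ratio scaling. These histone genes are near-identical copies whose reads the counting could split. The 36 mitosis genes had a median of 0.05 (percentile 12.06), or -0.14 with median-ratio scaling. Cenpf and Mki67 were at 0.95 and 0.91, and Aurkb and Cenpa at -0.59 and -0.53. For Mki67 the authors' deposited fold change, a ratio of FPKM values, has the opposite sign, at -0.27, and the cause was not tested.

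Lysosome genes had a median of 0.47 against 0.08 (percentile 100), with 17 of 41 at least 1.5-fold higher and 1 lower (10 and 1 with median-ratio scaling). Lipa, the lysosomal acid lipase, had 40 and 169 reads, a log2 ratio of 2.0 that is 2.76 in the authors' deposited table. Npc1, the cholesterol exporter of lysosomes, had 0 and 57 reads, at least 18.2-fold higher, on a fractional estimate. Tfeb and Tfe3, transcription factors of lysosomal genes, were at -0.78 and -0.26. Of 32 autophagy genes, 11 were higher by 1.5-fold and 1 lower (7 and 2 with median-ratio scaling), with a median of 0.35 (percentile 98.01). Atg4c had 23 and 53 reads, at 1.12. Atg10 was at -1.63 and Atg4d at -0.46. In the heat shock list 9 of 21 genes were higher by 1.5-fold and 0 lower, which became 3 and 1 with median-ratio scaling, with a median of 0.48 (percentile 100). Bag3, a co-chaperone, had 696 and 1570 reads, a ratio of 2.16, and Dnajb4 had 7 and 26, a ratio of 3.38. Fkbp4 was at -0.44 and Hsf1 at -0.24.

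Of the lists of neuronal genes, some stood apart and others did not. Of 26 presynaptic genes, 10 were higher by 1.5-fold and 0 lower (9 and 0 with median-ratio scaling), with a median of 0.41 (percentile 99.78) and Syt11 at 1.26. This list lay inside the middle 95% once the trend with transcript length was removed, with a difference of 0.18, but stayed above it among random lists matched on length too (percentile 98.96). The wider synaptic vesicle cycle pathway of 42 genes did not stand apart, with a median of 0.10 against 0.08 (percentile 60.0). Syn3 was at -0.36 and Cplx1 at -0.27. The 27 Parkinson and neurodegeneration genes had a median of 0.43 (percentile 99.93), with 10 higher and 0 lower by 1.5-fold (8 and 1 with median-ratio scaling). The wider pathways did not stand apart: Parkinson disease (percentile 97.05), Alzheimer disease (88.60), Huntington disease (70.55) and amyotrophic lateral sclerosis (30.80). Apoe had 6 and 43 reads, a ratio of 6.40, and Clu, a secreted chaperone, had 339 and 1239, a ratio of 3.49. Htra2 was at -0.43 and Park7 at -0.39. The 27 neurite and axon cytoskeleton genes had a median of 0.27 (percentile 99.16), with 10 higher and 1 lower by 1.5-fold (7 and 1 with median-ratio scaling), and Stmn4 at 1.94, Cntn2 at 1.47 and Nefh at -3.19 on 30 and 3 reads. In the authors' deposited table Cntn2 is at -0.045. With the authors' deposited fold changes this median exceeded that of matched lists by 0.007 and no longer lay outside the middle 95%. Calcium signalling genes had a median of 0.36 (percentile 97.61), with 6 higher and 1 lower by 1.5-fold (4 and 1 with median-ratio scaling), led by Atp2b4, a calcium pump of the cell membrane, at 1.67, with Itpr1 at 0.91, Cacna1h at -0.70 and Orai1 at -0.34. In the authors' deposited table Itpr1 is at -0.20 and Cacna1h at 0.00. This list lay inside the middle 95% once random lists were matched on transcript length too, with a difference of 0.11, with the length trend removed, with one of 0.14, and with the deposited fold changes, with one of 0.16. The wider calcium signaling pathway did not stand apart (percentile 81.95). Catecholamine genes had a median of 0.06 (percentile 25.20), or -0.12 with median-ratio scaling. In that list Slc18a2, the vesicular monoamine transporter, had 26 and 74 reads, a ratio of 2.69. Th, which makes the precursor of dopamine, had 88 and 173, a ratio of 1.88, while Spr was at -0.86. Glutamate and GABA genes had a median of 0.55 over 10 measured members (percentile 94.62), and neural progenitor genes one of 0.27 (percentile 78.16). With the deposited fold changes the glutamate and GABA list lay above the middle 95%.

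**Figure D2:**
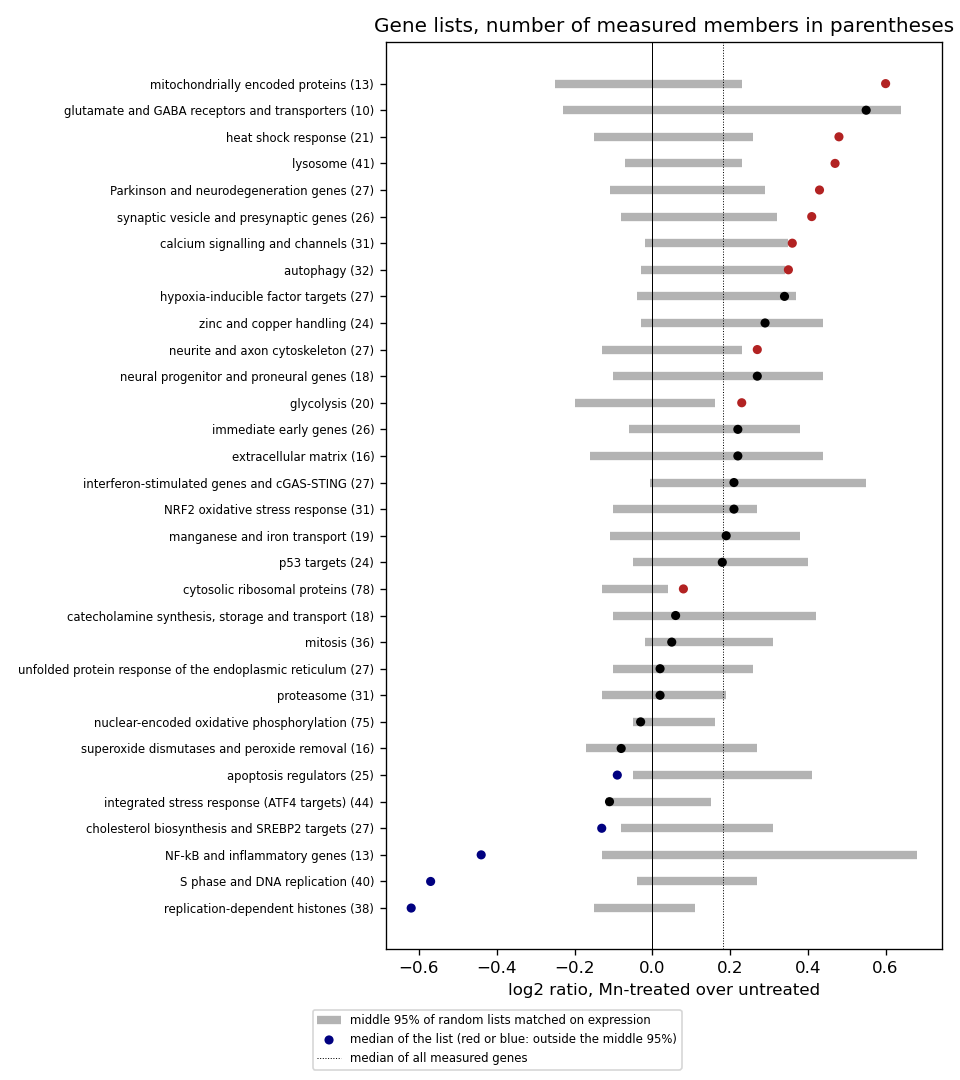
Median log2 ratio, Mn-treated over untreated (x axis), of each gene list with at least 5 measured members (rows); grey bars span the middle 95% of medians of random lists matched on expression, and the dotted line is the median of all genes, 0.18. Red points lie above and blue points below their bar, with replication-dependent histones lowest at -0.62 and mitochondrially encoded proteins highest at 0.60.

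Stress pathways did not share 1 direction. Integrated stress response genes had a median of -0.11 (percentile 3.57), which fell below the middle 95% with 5 expression bins or with the length trend removed, with Atf3 at 1.07 and Cebpg at 0.65, but the serine and glycine enzymes Psph and Shmt2 at -0.85 and -0.84. Genes of the unfolded protein response had a median of 0.02 (percentile 27.04), or -0.16 with median-ratio scaling, with Ero1l at 0.96 and Sdf2l1 at -0.94. The wider pathway of protein processing in the endoplasmic reticulum, of 148 genes, lay above the middle 95%. Its median was 0.20 against 0.10 (percentile 99.70), with 27 genes higher and 4 lower by 1.5-fold. NRF2 target genes had a median of 0.21 (percentile 89.96), but stood apart among lists matched on transcript length too (percentile 99.46) and with the length trend removed. Srxn1, which repairs peroxiredoxins, had 610 and 2004 reads, a ratio of 3.14, and Gstm1 had 476 and 1171, a ratio of 2.35, while Aldh3a1 was at -1.09 and Cbr3 at -0.90. The 16 superoxide and peroxide removal genes had a median of -0.08 (percentile 12.86), and all 16 lay within 1.5-fold. Targets of hypoxia-inducible factor had a median of 0.34 (percentile 94.67), with Bnip3 at 1.11. Glycolysis genes had a median of 0.23 against -0.02 (percentile 99.71), with 1 of 20 higher by 1.5-fold, the neuronal enolase Eno2 at 0.78. This list lay inside the middle 95% with the length trend removed, with a difference of 0.16, but stayed above it with length matching (percentile 99.23). The wider glycolysis and gluconeogenesis pathway did not stand apart (percentile 88.90). The 24 p53 target genes had a median of 0.18 (percentile 53.09), which became -0.004 with median-ratio scaling. The wider p53 signaling pathway of 55 genes lay below the middle 95%, with a median of -0.07 against 0.16 (percentile 0.10), 11 genes higher and 8 lower by 1.5-fold. Their members lay far apart. Bbc3, a trigger of apoptosis, had 80 and 5 reads, at -3.94, whereas Trp53inp1 was at 1.85 (2.95 in the authors' deposited table) and Ddb2 at 1.77. Of 25 apoptosis regulators 3 were higher and 3 lower by 1.5-fold (1 and 5 with median-ratio scaling), with a median of -0.09 against 0.18 (percentile 1.2). This list lay inside the middle 95% when only genes with at least 100 reads were used or the length trend was removed, each with a difference of -0.18, but stayed below it with length matching (percentile 1.18). The wider apoptosis pathway of 103 genes did not stand apart (percentile 16.10). The apoptosis pathway of multiple species, of 26 genes, lay below the middle 95%, with a median of -0.04 against 0.16 (percentile 2.40). Of its genes 4 were higher and 2 lower by 1.5-fold. Among the apoptosis regulators Bmf was at 0.93, Xiap at 0.69 and Casp9 at -0.63. In the authors' deposited table Bmf is at 0.39 and Xiap at 0.34, both within 1.5-fold, and Casp9 is at -0.63.

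Of 13 measured NF-kB and inflammatory genes, 6 were lower by 1.5-fold and 0 higher (7 and 0 with median-ratio scaling), with a median of -0.44 against 0.27 (percentile 0.03). The wider NF-kappa B signaling pathway of 52 genes did not stand apart, with a median of 0.18 against 0.22 (percentile 33.6), 9 genes higher and 4 lower by 1.5-fold. Vcam1 had 46 and 16 reads, at -1.56, and Cxcl1 had 53 and 20, at -1.45. The highest were Tnfrsf1b at 0.46 and Tnfaip3 at 0.43, both with intervals that included 0. Interferon-stimulated genes had a median of 0.21 (percentile 34.30), with 8 of 27 higher and 4 lower by 1.5-fold (8 and 5 with median-ratio scaling). Ifit1 had 0 and 38 reads, at least 12.1-fold higher, and Oasl2 was named above. Psmb9 was at -1.01 and Xaf1 at -1.32 on 15 and 6 reads, or -2.19 in the authors' deposited table. Immediate early genes had a median of 0.22 (percentile 69.78), with Egr2 at 1.98 on 11 and 47 reads and Nr4a1 at -0.94.

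Cholesterol synthesis genes had a median of -0.13 against 0.11 (percentile 0.86), with 3 higher and 3 lower by 1.5-fold (1 and 7 with median-ratio scaling). The steroid biosynthesis (percentile 24.20) and terpenoid backbone biosynthesis (percentile 5.60) pathways did not stand apart. Tm7sf2 and Mvk, enzymes of that pathway, were at -1.29 and -1.26, while Hmgcs1 was at 0.71 and Lpin1 at 0.89. The 13 mitochondrially encoded protein genes had a median of 0.60 against -0.01 (percentile 100), with 7 higher and 2 lower by 1.5-fold (2 and 2 with median-ratio scaling), and were unequal among themselves. Transcripts of mt-Nd6, the one protein gene on the light strand, had 3844 and 27864 reads, a ratio of 6.93, and mt-Nd2 had 1173 and 2844, a ratio of 2.32. In contrast mt-Co1 and mt-Co3, the most abundant of the 13, were at -0.98 and -0.97. Whether the counting used strand is not given in the sources used here, so reads of mt-Nd6 cannot be told apart from antisense reads. Nuclear-encoded oxidative phosphorylation genes had a median of -0.03 against 0.05 (percentile 5.98), with Ndufa1 at 1.06 and Cyc1 at -0.67. Among lists matched on length too, the direction turned, with -0.03 against -0.09 (percentile 85.67). The wider oxidative phosphorylation pathway of 116 genes did not stand apart (percentile 96.75). All 78 cytosolic ribosomal protein genes lay within 1.5-fold, with a median of 0.08 against -0.04 (percentile 99.90), which became -0.10 with median-ratio scaling. This list lay inside the middle 95% when 5 expression bins were used, but stayed above it with length matching (percentile 100). The wider ribosome pathway of 128 genes lay above it too, with a median of 0.05 against -0.10 (percentile 100), 2 genes higher and 4 lower by 1.5-fold. Proteasome genes had a median of 0.02 (percentile 45.49), or -0.17 with median-ratio scaling, and extracellular matrix genes one of 0.22 (percentile 73.69), which stood apart when only genes with at least 100 reads were used.

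Markers of other cell types were few. Measured were 4 of 10 astrocyte, 1 of 12 microglia and macrophage, 3 of 10 oligodendrocyte, 3 of 10 fibroblast and 4 of 10 endothelial markers, with medians of -0.12, -0.31, 0.25, 0.22 and 0.21. S100a4 of the fibroblast list had 4 and 36 reads, a ratio of 7.76, while Col1a1 had 42 and 33. The authors' deposited table of the same 2 libraries held 7115 mRNA genes at a false discovery rate below 0.05, of which 1031 were at least 2-fold higher and 239 at least 2-fold lower with manganese.

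The second comparison asked the same of lncRNA transcripts. Of 3406 transcripts with at least 20 reads, 844 were at least 2-fold higher and 361 at least 2-fold lower in the Mn-treated library, against 46.3 and 49.7 from counting noise alone. Counting noise leaves out error in dividing reads among transcripts that share them. The counts are estimates, so the excess over counting noise cannot be read as a number of changed lncRNAs. The median log2 ratio was 0.33, and scaling by the median ratio gave 611 higher and 497 lower. A single transcript, ENSMUST00000192833, held 64.4% of the lncRNA reads of the untreated and 59.9% of those of the Mn-treated library, and therefore weighs on that scale. ENSMUST00000057216 had 0 and 262 reads, at least 96.3-fold higher, and ENSMUST00000133266 had 0 and 248. ENSMUST00000206229 had 250 and 0 reads, at least 75.6-fold lower, and ENSMUST00000141128 had 238 and 0. Counts of every transcript named here were fractional in one library or both, so these values are uncertain too. The deposited files do not pair transcripts with gene names, so the list of named lncRNAs was not analysed on this table. One of its members, Snhg4, was in the mRNA table with 3 and 22 reads. The authors' deposited table held 1919 transcripts at a false discovery rate below 0.05, with 930 at least 2-fold higher and 484 at least 2-fold lower.

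The third comparison was of circRNAs, which were thinly covered. Of 2253 circRNAs, 999 had junction reads in both libraries, 730 in the untreated library alone and 524 in the Mn-treated library alone, and the median over both libraries was 5 reads. By annotation 1856 joined annotated exons, and the rest came from single exons, exon and intron, introns, antisense or intergenic sequence. Of 534 with at least 10 junction reads, 97 were at least 2-fold higher and 121 at least 2-fold lower with manganese, and counting noise alone gave 39.1 and 38.1. The interval of the ratio excluded equality for 51 and 69 of them. Coordinates are those of the authors' table. The highest was a circRNA of exons of Rps6ka2, a ribosomal S6 kinase, on chromosome 17 from 7227913 to 7271656, with 0 and 16 reads, at least 6.60-fold higher. Next were exonic circRNAs of Phtf2 on chromosome 5 from 20789629 to 20794481 and of Mbtps2, a protease that activates SREBP, on chromosome X from 157558885 to 157591555, each with 0 and 14 reads. An exonic circRNA of Phip had 0 and 13 reads, and one of exon and intron sequence of Gm15398 had 0 and 12. The lowest was an exonic circRNA of Ldah on chromosome 12 from 8268364 to 8275890, with 17 and 0 reads, at least 4.58-fold lower. Exonic circRNAs of Pafah1b2, Nmd3 and Tmem56 had 16, 14 and 12 reads without and 0 with manganese, and an intergenic circRNA on chromosome 8 from 41682056 to 41685995 had 12 and 0.

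Whether a circRNA moved with the mRNA of its host gene was asked over 504 circRNAs with a measured host. Across circRNAs, which are not independent replicates, Spearman's rho between both log2 ratios was 0.01, and it was 0.14 over the 46 with at least 50 junction reads. The spread of the circRNA ratios (SD 1.61 across circRNAs) was wider than that of the host ratios (SD 0.58), to which counting noise on few reads adds, and the SDs were 0.69 and 0.38 over the 46. The authors' deposited table marked 374 circRNAs as significant, 149 higher and 225 lower, of which 271 had 0 reads in one library, and 25 of the 374 had a false discovery rate below 0.05.

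The fourth comparison was of miRNAs. miR-129-5p, an miRNA of neurons, and miR-210-3p, which hypoxia induces, were higher in the Mn-treated library, and the median of the imprinted Dlk1-Dio3 cluster on chromosome 12 was lower. Of 605 known miRNAs with at least 20 reads, 38 were at least 2-fold higher and 28 at least 2-fold lower, against 3.22 and 3.44 from counting noise. With median-ratio scaling the numbers were 33 and 41, and the median log2 ratio of 0.07 became -0.006. Highest among miRNAs with at least 50 reads in the higher library was miR-129-5p (CTTTTTGCGGTCTGGGCTTGC). It had 878 and 3655 reads, a ratio of 4.39 [4.07 to 4.73]. miR-8103 had 21 and 85 reads, miR-8114 had 30 and 113, and miR-330-3p had 23 and 74, with ratios of 4.19, 3.92 and 3.34. miR-210-3p had 99 and 294 reads, a ratio of 3.12 [2.48 to 3.97], and miR-182-5p had 40 and 115, a ratio of 3.01. Lowest under the same limit were miR-466i-5p at -2.17 on 59 and 12 reads, miR-199b-5p at -1.66 on 610 and 183 [-1.91 to -1.42], and miR-380-3p at -1.60. miR-669g was at -1.46, miR-574-5p at -1.45 on 397 and 138 reads, and miR-362-3p at -1.43. The 5 most abundant miRNAs held 45.1% and 43.8% of the reads. miR-881-3p and miR-7a-5p were at -0.25 and -0.24, and miR-21a-5p, miR-143-3p and miR-871-3p at 0.42, 0.27 and 0.29.

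**Figure D3:**
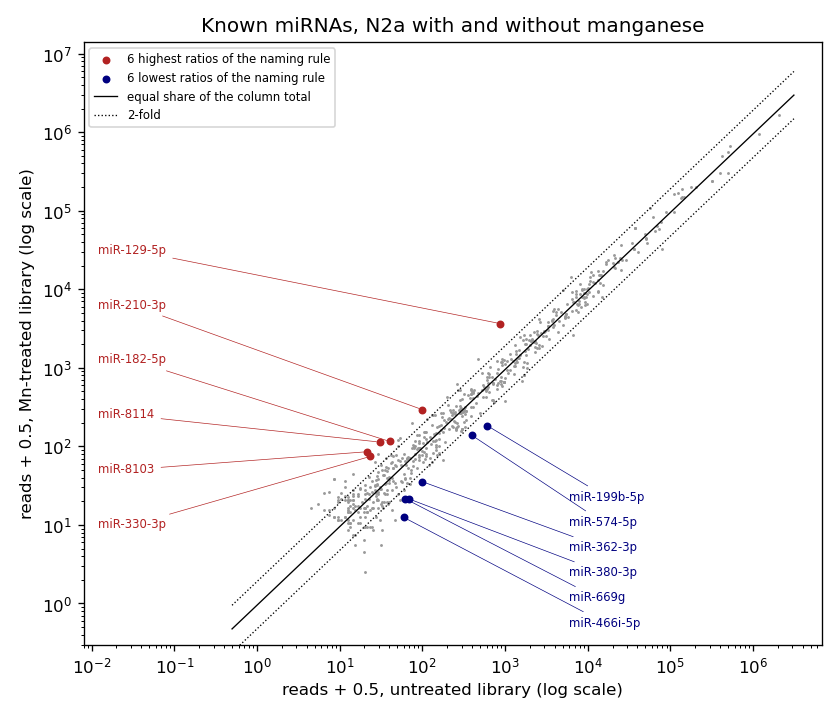
Reads plus 0.5 per known miRNA in the untreated (x axis, log scale) and the Mn-treated small RNA library (y axis, log scale), 1 grey point per measured miRNA. Lines are as for the mRNA genes, and the named points are the 6 highest (red) and 6 lowest (blue) of the naming rule, with miR-129-5p at 878 and 3655 reads.

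Of 7 miRNA lists fixed beforehand, 1 lay above and 1 below the middle 95% of matched lists, where chance gives 0.35. The 35 measured miRNAs of the Dlk1-Dio3 cluster had a median of -0.49 against 0.10 (percentile 0.00), with 13 lower and 2 higher by 1.5-fold (17 and 2 with median-ratio scaling). These miRNAs come from 1 genomic cluster and are not independent, whereas the random lists drew from all measured known miRNAs. The percentile is therefore a description only. miR-382-3p had 180 and 66 reads, at -1.36, and miR-494-3p had 24 and 9, at -1.29. miR-299a-5p had 7 and 26 reads, at 1.90, but the other arm, miR-299a-3p, was at -0.83 on 296 and 158 reads. miR-377-3p was at 0.79 with an interval that included 0. The 9 hypoxia and stress miRNAs had a median of 0.45 (percentile 98.50), with 3 higher and 1 lower by 1.5-fold (1 and 1 with median-ratio scaling). Beside miR-210-3p, miR-214-3p was at 0.66 and miR-146a-5p, an NF-kB-induced miRNA, at -0.63. The let-7 family had a median of 0.24 (percentile 86.61), and all 9 members lay within 1.5-fold. Neuronal miRNAs had a median of 0.02 (percentile 38.45), or -0.06 with median-ratio scaling, with miR-9-3p at 1.05, miR-134-5p at -0.82 and miR-218-5p at -0.63. Medians were 0.11 for miR-17-92 and its paralogs (percentile 69.92), 0.19 for p53-linked miRNAs (percentile 74.97) and 0.10 for the miR-183, miR-200 and miR-15/16 groups (percentile 61.48). Over 166 hairpins with both arms measured, Spearman's rho between the ratios of the 5p and the 3p arm was 0.27, and 101 hairpins had arms of the same sign. Both arms were past 2-fold in 2 of these hairpins, and in 0 of the 110 whose arms each had at least 100 reads. The ratio of a single arm named above therefore does not stand for its hairpin. Hairpins are not independent replicates.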

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

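Small RNAs that carry an miRNA name without the mouse prefix were not used in the comparisons and stood out as a signal above the untreated library. They made up 8.004% (Wilson 95% interval 7.987 to 8.021) of the reads in the table of the Mn-treated library and 6.906% (6.891 to 6.922) of the untreated one, over 802 names. The intervals cover counting error only, and no explanation was tested. Predicted new miRNAs made up 0.127% and 0.126%.

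Technical explanations were weighed for 3 patterns, all picked after the data had been looked at. Chosen after their result was seen were the tests of genomic span, of read number, of the library scalings and of the mitosis genes. No replicate exists, so a difference between 2 cultures or 2 library preparations stays open for each pattern, and manganese is the biological explanation that the design names, untested against it.

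The first pattern is that longer mRNAs were higher in the Mn-treated library. The median log2 ratio went from -0.04 in the shortest of 10 equal bins of 9133 genes to 0.47 in the longest. Lower read numbers of long mRNAs were argued against, since the relation kept a rho of 0.362 within 10 bins of read number. A bias that acts on the length of the mature transcript alone was argued against only in part. The ratio still followed genomic span within 10 bins of transcript length (rho 0.262). It also followed transcript length within bins of genomic span (rho 0.182). Transcript length was implied from count over FPKM, and error in it could leave some relation with span. A difference in fragment size or RNA integrity between the libraries may still contribute, because rho among lncRNA transcripts was 0.019, between the values that would have decided.

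The second pattern is that replication and histone genes were lower. The length trend was argued against, since the S phase list stayed at percentile 0.0 among lists matched on both reads and length. The scaling was argued against for the rank of that list, which no scaling changes. Its median was -0.57 with column totals, -0.76 with median-ratio scaling and -0.75 with TMM. Median-ratio scaling and TMM lower every ratio, so they could not have raised the median. Scaling by mRNA plus lncRNA totals, which raises the ratios, was not computed for this list. The mitosis genes did not fall as far as the S phase list, with a median of 0.05. They still lay below the 0.14 of lists matched on reads and length, at percentile 13.36. The wider cell cycle pathway of 114 genes was at 0.004 against 0.13 (percentile 0.30), with 11 genes higher and 14 lower by 1.5-fold. A percentile of 13.36 cannot exclude a modest fall, so fewer cycling cells of every phase stay open. A smaller share of cells in S phase with manganese may account for the second pattern. This hypothesis was found on these same 2 libraries and is left open. DNA content or labelling of new DNA, which would decide it, was not analysed here.

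The third pattern is the 18 mRNA genes with 0 reads in one library and at least 50 in the other, 10 higher and 8 lower with manganese. Chance in sampling reads was argued against, since counting noise gave 0.0 such genes on average. Estimated counts that move between gene models sharing reads may account for most of them: 88.9% of these genes (exact interval 65.3 to 98.6) had a fractional count, and 17.1% of 2009 genes of like read number had one. Kif3b and Adcy4 had whole counts, so this leaves them open.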

How the results depend on the processing

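Chosen after seeing the data were the length-corrected values, the totals of mRNA plus lncRNA, the leaving out of unsteady genes, the deposited fold changes of named genes and the use of every small RNA. Values are higher, then lower, features past 2-fold, and where a count moved by over 1.5-fold the cause was not tested unless the setting itself changes which features are counted. For mRNA genes (862 and 202), median-ratio scaling gave 546 and 327, and TMM 555 and 322. With no lower limit on counts the numbers were 2090 and 783 for mRNA genes, 3363 and 2207 for lncRNAs, 751 and 894 for circRNAs and 160 and 143 for miRNAs. With a limit 5 times as high they were 485 and 75, 202 and 54, 6 and 1, and 18 and 8. For circRNAs (97 and 121), a prior of 5 counts gave 63 lower, and the intervals that exclude equality left 51 and 69. For miRNAs (38 and 28), adding predicted new ones gave 50 lower, and every small RNA of the table gave 92 and 71. TMM gave 42 lower miRNAs, exactly 1.5-fold, and the remaining settings moved these counts by less. The rho of circRNA and host ratios was 0.14 with at least 50 junction reads. Hist1h4i turned from 0.06 to -0.12 with median-ratio scaling and -0.11 with TMM. With the authors' deposited fold changes Mki67 turned to -0.27, Cntn2 to -0.045 and Itpr1 to -0.20, and the cause was not tested. Of the other settings for gene lists, 166 left a list on its side of the middle 95%, 9 moved it inside and 6 moved it outside. None turned the direction of a list that stood apart. Turns of lists inside the middle 95% were not counted. Nuclear-encoded oxidative phosphorylation genes were such a case, since they went from below to above their random lists with length matching. Moved inside were calcium by 3 settings, apoptosis by 2, and presynaptic, glycolysis, neurite and ribosomal protein genes by 1 each. Moved outside were NRF2 and integrated stress response genes by 2 each, and glutamate and GABA and extracellular matrix genes by 1 each. For named features 639 values stayed within their counting interval and 173 left it in the same direction or without a call. Depth limits the circRNAs most, with a median of 5 reads.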

Other observations

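The pathway annotation in the mRNA table was ranked in the same way after the lists had been seen, with 1000 random lists matched on reads and transcript length for each of 268 pathways of 15 to 250 measured genes. Below the middle 95% lay 24 and above it 28, where chance gives 6.7 on each side. Pathways overlap, so these are not independent. Beside DNA replication, with a median of -0.45, the lowest included folate-dependent one-carbon metabolism, which supplies nucleotide synthesis, at -0.31 with 5 of 17 genes at least 1.5-fold lower and 0 higher. Base excision repair was at -0.24, the Fanconi anemia pathway at -0.14 and homologous recombination at -0.13, each with a matched median between 0.10 and 0.21. Pyrimidine metabolism was at -0.15 over 87 genes. On the other side, other glycan degradation, a set of lysosomal enzymes, was at 0.43 over 15 genes, antigen processing and presentation at 0.32 over 34, and phagosome genes at 0.28 over 80. SNARE proteins of vesicle transport were at 0.36 over 30 genes, at percentile 97.40 and thus inside the middle 95%. The dopaminergic, glutamatergic and GABAergic synapse pathways lay above it (percentiles 98.90, 98.80 and 99.0), and axon guidance lay inside it (89.20).

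Across the 605 known miRNAs the log2 ratio had a Spearman's rho of 0.19 with GC content and of 0.07 with length. Between the libraries the implied transcript length differed by over 1.5-fold for 495 of 11042 genes. Of lncRNA transcripts, 46 had 0 reads in one library and at least 50 in the other.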
